A study of Canis lupus familiaris and Eptesicus fuscus and Equus caballus with 6 samples.

How the data were processed

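Adult testes of dog, horse and big brown bat (Eptesicus fuscus) gave 2 kinds of library, a small RNA library and an mRNA library, so that each of the 6 groups held 1 library. Per the labels' protocols, total RNA was extracted with TRIzol from frozen tissue, and the small RNA fraction was sequenced as single-end reads of 50 nt. The submitters' processing notes name Bowtie and RSEM without versions, and the build CanFam3.1 for every sample, bat and horse included. The build used for bat and horse, the trimming and the length selection are not given in the sources used here. No genome or element consensus sequence was used, so the placement of piRNAs on elements or genes was not analysed here.

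Each small RNA file, as deposited by the authors, holds distinct sequences with a raw read count. Every listed sequence was 24 to 32 nt long in the 3 files, so the 20 to 23 nt class fixed before the data were examined could not be described, and widening the piRNA class to 24 to 33 nt would take all reads. A sequence found on more than 1 row was summed. The total of a file is therefore the number of reads of these lengths and not the full depth of the library. The piRNA size class was 26 to 32 nt. Shares of reads carry exact (Clopper-Pearson) 95% binomial intervals. Reads were PCR copies without molecular identifiers, so intervals and floors cover counting error only. The smallest share that 3 reads allow was 7.26e-06% in dog, 5.15e-05% in bat and 8.37e-06% in horse.

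Known RNAs were in part listed as their reverse complement. In the 3 files no sequence was listed together with its own reverse complement, and the tRNA-Gly-GCC 5-prime fragment was written in RNA sense for 1505574 reads in dog but as its reverse complement for 335108 reads in horse. A second version of each sequence measure was therefore made after seeing the data. It rests on piRNAs having a fixed 5-prime end and a variable 3-prime end. Each sequence was linked, step by step, to the most abundant sequence sharing its first or last 24 nt. The group was read as listed where at least 80% of the reads of its leading sequence's variants (at least 10 reads) shared the first 24 nt, and reversed where at least 80% shared the last 24 nt. No base identity enters this rule. It oriented 57.5% of the 26 to 32 nt reads in dog, 62.8% in bat and 51.1% in horse, of which 46.2%, 45.5% and 51.3% were reversed. Checked on known RNAs, it was right for 100.0% of tRNA sequences in the 3 species, for 91.3% of miRNA sequences in dog and 100.0% in bat and horse, but for only 71.9%, 39.3% and 46.2% of rRNA sequences in dog, bat and horse. By reads it was right for 76.4% of the oriented miRNA reads in dog, and for 91.3%, 9.70% and 69.6% of the oriented rRNA reads in dog, bat and horse, which in bat were 349014 reads. Linked sequences share the call of their leading sequence, so these percentages do not rest on independent sequences. The tRNA sequences all came from the 5-prime fragments of tRNA-Gly-GCC and tRNA-Glu-CTC.

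Overlap of complementary sequences was counted over distinct sequences of 26 to 32 nt, each overlap judged on 10 nt of complementarity, and given as the number of pairs at 10 nt over the median at 11 to 24 nt. Its error is the range over 20 random draws of 50% of the distinct 5-prime ends. Known small RNAs were searched on both strands with 33 conserved miRNAs, 5-prime fragments of tRNA-Gly-GCC and tRNA-Glu-CTC, and 5S and 5.8S rRNA, listed before the data were examined. On simulated data the orientation rule was right for 100.0% of the sequences it oriented. The first-base U share came back as 67.3% for a true 67.3%, and the overlap ratio as 20.4 for a true 20.4. Simulated data without partners gave a ratio of 1.15, over 121821 sequences, so a ratio of this size can arise without partners. Without starts that are their own reverse complement the same data gave 1.08. The simulated values do not bound the errors of the orientation rule on real RNAs, since many known rRNA sequences were oriented wrongly.

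Each mRNA file holds RSEM output per repeat family. The TPM values and their interval bounds were deposited by the authors, per the file headers, and are scaled to the same sum over the models of each file alone. The dog file held 955 models and the horse file 986, with rRNA, tRNA, snRNA, satellites and simple repeats among them, and the bat file held 511 element models only, so TPM of bat is not on the scale of the others. For bat, the expected counts deposited by the authors were used, and their ratio to TPM followed the model length minus 24.0 nt, with a largest deviation of 0.0225% over 217 families. For dog and horse no expected count was used here, and reads were rebuilt as TPM times the length minus 24 nt, divided by the commonest low value. In these files alone the share of low families (under 20.5 reads) within 0.05 of a whole number peaked at an offset of 24 nt in dog and 25 nt in horse. With 24 nt it was 53.7% in dog and 51.4% in horse, against 41.7% for the deposited expected counts of bat. On simulated counts for the dog and horse models, 100.0% of rebuilt counts came back within 1% of the simulated count. A simulated 4-fold change came back as a median of 1.99 on the log2 scale over 77 families in dog and 2.00 over 143 families in horse. These medians include the shift of the TPM scale, which was known from the simulated counts and added back. The horse over dog TPM ratios below carry no such correction, so the simulation did not test the scale between files. The simulated TPM was made with the same 24 nt, so the simulation did not test this offset. Counts for dog and horse are called rebuilt reads below. Intervals on them use the counts rounded to whole numbers.

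Element classes were taken from the file IDs and merged to LINE, SINE, LTR, DNA transposon, Helitron and unknown. Shares are of the reads on elements. Families named alike were compared as log2(TPM + 1), and against bat as TPM rescaled to elements alone. With 1 library per group no test between species was made, no p-value is given, and a difference between species is a difference between libraries. Families named in the text are, by a rule fixed before the data were examined, the 10 with most reads per species, the first of each class, and for families named alike the 5 with the largest fold in each direction with at least 50 reads in the higher species. For small RNA they are the 3 most abundant sequences per size class and the 5 known RNAs with most reads. Other names were chosen after their values were seen and are said to be. The fixed gene and cell type lists were not used, since the mRNA files hold repeat families and not genes. Alternatives covered reads against distinct sequences, read minimums, a 28 to 31 nt class, removal of known RNAs, equal numbers of sequences, TPM against reads, minimums on reads, removal of the leading family and the pseudocount. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.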

Results

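Testis small RNA and mRNA were sequenced from dog, big brown bat and horse, taxa that the study describes as differing in transposable element activity, to ask how piRNAs target elements. piRNAs are the small RNAs that guide PIWI proteins against transposable elements in the germ line. Each species had 1 small RNA and 1 mRNA library, so that no difference below has a replicate check. The small RNA files held 41328689 reads of 2937574 distinct sequences in dog, 5828928 reads of 635917 sequences in bat and 35830283 reads of 3971863 sequences in horse. The mRNA files held 679617 rebuilt reads on repeat models in dog, 55904 expected counts in bat and 666103 rebuilt reads in horse.

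Within the 24 to 32 nt that the small RNA files list, reads of the 3 testes were most often 29 or 30 nt long. Dog reads were most often 30 nt (30.9%, 95% interval 30.93 to 30.96%) or 29 nt (29.1%) long. Horse reads also were most often 30 nt long (30.8%), with 21.1% at 29 nt and 16.9% at 31 nt. In bat, 29 nt (28.9%) and 30 nt (28.6%) were nearly level. The 26 to 32 nt class held 98.1% of the dog reads, 94.5% of the bat reads and 95.8% of the horse reads. The widest of these 3 intervals, in bat, ran from 94.4 to 94.5%. These shares are largely set by the listed lengths, and shorter or longer RNA was not analysed here.

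**Figure D1:**
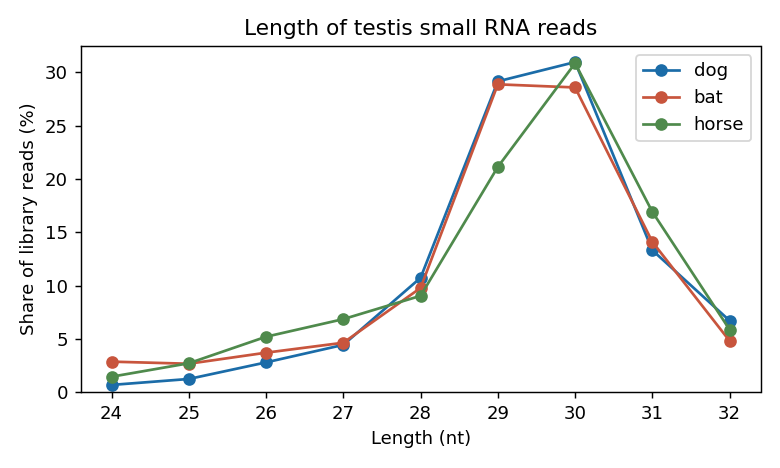
Length (nt, x axis) against the share of library reads (%, y axis) in the dog, bat and horse small RNA libraries, 1 line per library. Dog and horse peak at 30 nt (30.9% and 30.8%), and bat at 29 nt (28.9%).

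Reads were spread over many sequences in each testis. The 10 most abundant sequences of 26 to 32 nt took 9.04% of the reads of that class in dog, 11.5% in bat and 4.63% in horse, and the 1000 most abundant took 42.3%, 44.3% and 29.1%. The leading sequence in dog was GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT, the 5-prime fragment of tRNA-Gly-GCC, with 1317469 reads (3.19% of the library). It was followed by TTAATGACCTTCATGGACGCCTCTGACCC with 421092 reads (1.019%) and by TTGGAGACAGAACAGGATCTAACTTGGGCC with 383916 reads (0.929%). In bat, a single sequence listed as TCTGACAGTTCTAGGTCCAGAAAACGCAA took 253037 reads (4.34%); by its length variants it was listed as the reverse complement of an RNA that begins with U. The next sequences in bat were 5S rRNA fragments of 32 and 31 nt, with 69190 and 62291 reads. In horse the leading sequence, listed as ACTCTTGAGTGGGTTTGAAGTCTGGTCTTA, held 310724 reads (0.867%) and was again the reverse complement of an RNA that begins with U. The sequence TGAGAAGTTCGTTAGGATGTCGCACTCCT and its form longer by 1 base held 198768 and 177129 reads in horse.

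Other small RNA classes differed between the libraries. The tRNA-Gly-GCC 5-prime fragment, a common product of tRNA cleavage, made up 3.64% of the dog reads, 0.935% of the horse reads and 0.195% of the bat reads. Fragments of 5S rRNA made up 6.09% of the bat reads (6.07 to 6.11%), against 0.0634% in dog and 0.141% in horse. The tRNA-Glu-CTC fragment was at 0.110% in dog, 0.219% in bat and 0.104% in horse. Among forms of 24 nt or longer, miR-10b-5p led the listed miRNAs in dog (24067 reads) and horse (31412 reads), and miR-30a-5p in bat (5119 reads). miR-30a-5p had 10417 reads in dog, and miR-21-5p had 2589 reads in bat and 17087 in horse. All listed miRNAs together were 0.111% of the reads in dog, 0.175% in bat and 0.183% in horse. At 24 to 25 nt, TGAGAACTGAATTCCATAGGCTGT led in dog with 47289 reads, TACCCTGTAGAACCGAATTTGTGT (miR-10b-5p) in horse with 31333 reads, and AATTGTTTCAAGACGGGACTGATG in bat with 41627 reads.

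A first-base U is the mark of primary piRNAs. As listed, the first base was T in 50.99% of the 26 to 32 nt reads in dog, 48.9% in bat and 48.1% in horse, where the mean over the other positions was 26.9%, 25.4% and 26.3%. The last base was A in 44.6%, 47.5% and 51.5% of the reads. After the listed sequences were oriented by their length variants, a step added after seeing the data, the first base was U in 64.9% of the oriented reads in dog, 71.8% in bat and 77.3% in horse. Without known tRNA, rRNA and miRNA sequences these shares were 69.4%, 79.3% and 78.9%. Over all oriented reads the last base was A in 28.1%, 26.8% and 25.1%. Over distinct oriented sequences the share of first-base U was 52.0% in dog, 58.9% in bat and 57.8% in horse. At 32 nt, U stood first in 16.1% of the oriented reads in dog, 33.6% in bat and 55.6% in horse, and in 52.6%, 61.8% and 60.7% of the distinct sequences. Known fragments not beginning with U held many reads of this length. In dog the tRNA-Gly-GCC fragment, beginning with G, held 1317469 of all 2773032 reads of 32 nt. In bat a 5S rRNA fragment, oriented with A first, held 69190 of 280542.

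**Figure D2:**
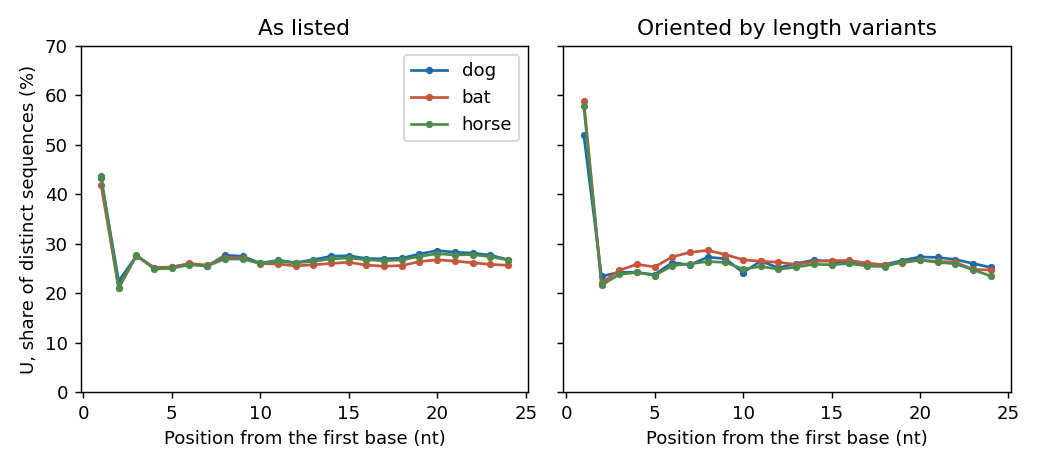
Share of distinct 26 to 32 nt sequences with U (%, y axis) at each position from the first base (x axis, nt), as listed (left) and after orientation by length variants (right), 1 line per library. At the first position the share is 43.3% (dog), 42.0% (bat) and 43.7% (horse) as listed and 52.0%, 58.9% and 57.8% after orientation.

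An A at position 10 and a 10-nt overlap between complementary 5-prime ends mark the ping-pong cycle, in which piRNAs of both strands of an element produce each other. As listed, A stood at position 10 in 30.1% of the dog reads, 25.4% of the bat reads and 28.5% of the horse reads, where the mean of the neighbouring positions (5 to 9 and 11 to 15) was 27.6%, 26.5% and 27.7%. Among oriented distinct sequences that did not begin with U, A at position 10 made up 35.3% in dog (35.1 to 35.6%), 28.1% in bat (27.7 to 28.6%) and 33.9% in horse (33.7 to 34.1%). The mean of the neighbouring positions of these sequences was 28.3% in dog, 26.4% in bat and 28.4% in horse. Over all oriented distinct sequences, position 10 held A in 34.6% in dog, 26.5% in bat and 31.4% in horse. This was above both adjacent positions in the 3 species, with 26.7%, 23.4% and 26.1% at position 9 and 27.9%, 24.6% and 26.8% at position 11. Position 5 held A in 32.1% in dog, 29.3% in bat and 34.2% in horse, more than position 10 in bat and horse, and position 13 in bat held 26.63% against 26.46% at position 10.

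Pairs that overlapped by 10 nt were in larger excess in dog and horse than in bat, except that the dog and bat ranges overlapped with 1 sequence per 5-prime end, and that bat was not lowest where each 10-nt start was counted once. As listed, the ratio of pairs at 10 nt to the median at 11 to 24 nt was 1.13 in dog, 1.09 in bat and 1.26 in horse. Among oriented sequences it was 2.93 in dog (range over draws of 5-prime ends 2.51 to 3.42), 1.28 in bat (1.15 to 1.47) and 4.78 in horse (3.88 to 5.68). The highest ratio at any other overlap was 1.33, 1.15 and 2.24. With 95% of variant reads required on one end, dog (6.41) and horse (6.47) were nearly level and bat was at 2.09, where the highest other overlap gave 1.76, 1.85 and 1.34. With all oriented sequences reversed, so that 3-prime ends were compared, the ratio was 0.989, 0.999 and 1.01. The excess rested largely on sequences that share a 5-prime end. With 1 sequence per 5-prime end the ratio was 1.15 in dog (1.13 to 1.17) and 1.43 in horse (1.36 to 1.50). There the highest other overlap gave 1.07 and 1.26. In bat the ratio was 1.05 (1.021 to 1.13), below the 1.12 at another overlap, so that no excess was detectable in bat. The ratios of this setting leave out starts that are their own reverse complement (self-complementary starts), whereas the ranges keep them. With each 10-nt start counted once, the ratio was 0.946, 0.969 and 0.9504 as listed and 1.0204, 1.03 and 1.003 oriented in dog, bat and horse. The listed sequences filled 59.6%, 25.1% and 67.0% of the 1048576 possible starts, which limits this measure as listed, and the oriented ones filled 12.01%, 3.40% and 14.7%.

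A small number of complementary starts held many of the pairs, and these examples were chosen after their values were seen. In horse, 1102 sequences that began with TTCTAGTTGT (51579 reads) faced 584 sequences that began with ACAACTAGAA (9438 reads), and this pair of starts held 29.9% of the 10-nt pairs. Their most read members were TTCTAGTTGTGGCATGTGGGACGCTGCCT and ACAACTAGAAGAACCCACAGCGAAGAATAC. In dog the leading starts, TCACAGAGGA with 344 sequences and TCCTCTGTGA with 116, held 5.47% of the pairs. In bat the starts TCTAGTTGTA and TACAACTAGA, with 63 and 6 sequences, held 1.97%. The 100 starts with most pairs held 55.5% of them in dog, 22.7% in bat and 80.8% in horse. Without these starts the ratio was 1.48 in dog, 1.04 in bat and 1.30 in horse. The starts were picked by their number of 10-nt pairs, so a lower ratio without them follows largely from that choice.

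**Figure D3:**
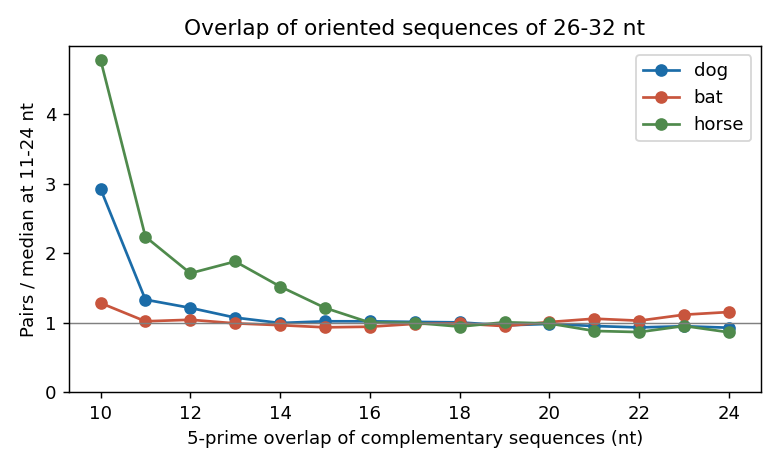
Number of complementary pairs of oriented 26 to 32 nt sequences, divided by the median at 11 to 24 nt (y axis), against the overlap of their 5-prime ends (x axis, nt), 1 line per library. At 10 nt the ratio is 4.78 in horse, 2.93 in dog and 1.28 in bat, and the grey line marks 1.

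Under 1% of distinct piRNA-sized sequences were shared between species. As listed, 0.350% of the smaller set was found in both dog and bat, 0.253% in dog and horse, and 0.301% in bat and horse. On either strand the shares were 0.602%, 0.496% and 0.652%. By reads, the sequences shared on either strand took 5.29% of the dog and 7.93% of the bat reads of this size for dog and bat, 6.44% of the dog and 3.603% of the horse reads for dog and horse, and 8.40% of the bat and 2.55% of the horse reads for bat and horse. As listed these parts were 4.58% and 2.38%, 0.784% and 0.557%, and 0.882% and 0.706%. Without the shared sequences that matched the listed tRNA, rRNA or miRNA sequences, the parts on either strand, of the same totals, were 1.39% of the dog and 1.78% of the bat reads, 2.55% of the dog and 2.39% of the horse reads, and 2.19% of the bat and 1.34% of the horse reads, and as listed 0.745% and 1.32%, 0.717% and 0.452%, and 0.856% and 0.702%. On either strand 1814 sequences of 26 to 32 nt were found in the 3 species, of which 342 matched the listed tRNA, rRNA or miRNA sequences.

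LINEs took most of the element reads in dog and horse, while in bat DNA transposons and Helitrons together took more reads than LINEs, SINEs or LTR elements. LINEs, the autonomous retrotransposons that include L1, took 71.3% of the element reads in dog (71.1 to 71.6%) and 71.5% in horse (71.3 to 71.7%). In bat they took 24.05% (23.7 to 24.4%). SINEs, the short elements copied by LINE proteins, took 23.3% in dog, 16.8% in horse and 14.0% in bat. DNA transposons and Helitrons together took 43.7% in bat (43.3 to 44.1%), against 1.42% in dog and 1.48% in horse. Helitrons, the rolling-circle transposons, alone took 17.6% in bat, while none of the 4 Helitron models of dog or horse had a read, where a floor of 3 reads is a share of 0.00289% in dog and 0.00172% in horse and the exact 95% intervals end at 0.00355% and 0.00211%. LTR elements took 3.95% in dog, 13.4% in bat and 10.2% in horse. The models differed between the files: bat had 85 Helitron, 143 DNA transposon and 25 LINE models, against 4, 205 and 146 in dog and 4, 202 and 138 in horse. As shares of TPM, which weighs short models more, SINEs led in the 3 species, with 76.6% in dog, 38.7% in bat and 71.6% in horse, and LINEs took 20.7%, 2.07% and 15.01%.

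**Figure D4:**
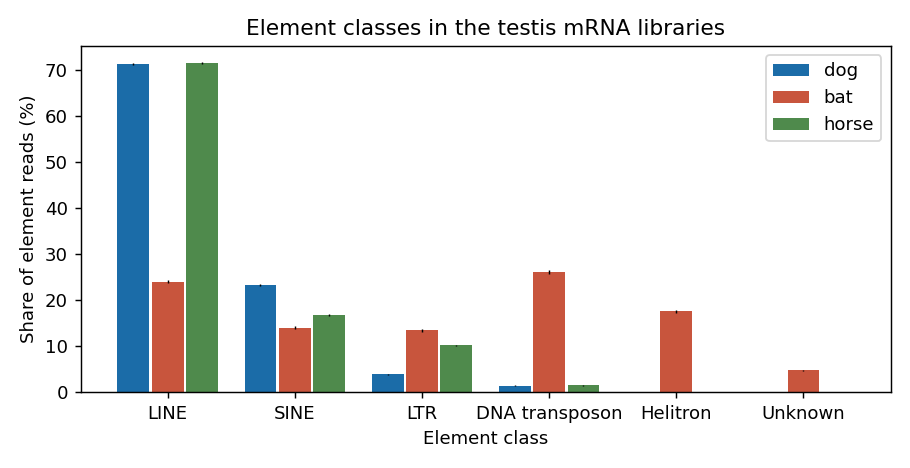
Share of element reads (%, y axis) by element class (x axis) in the dog, bat and horse mRNA libraries, bars from 0, with exact 95% binomial intervals that cover counting error only. LINEs hold 71.3% in dog, 24.05% in bat and 71.5% in horse, and DNA transposons 1.42%, 26.1% and 1.48%.

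In dog the leading element models were parts of young L1 families and SINEC, the tRNA-Lys-derived SINE of carnivores. L1_Cf_orf2 had 14179 rebuilt reads (13.7% of element reads), L1_Canis1_orf2 had 11901 (11.5%), L1_Canis1_3end had 10391 (10.01%) and L1_Canis2_orf2 had 8923 (8.60%). L1_Cf_3end followed with 5534 reads, and L1_Cf_5end with 4028. SINEC_Cf had 7907 reads (7.62%), and SINEC_a1 had 4070. The first LTR element was CfERVF2 with 831 reads (0.801%), and the first DNA transposon Tigger1 with 613 reads (0.590%). In 2 families chosen after their values were seen, TPM was higher toward the 3-prime part of the L1 models, going from the 5-prime over the orf2 to the 3-prime models from 3888 over 10079 to 14637 in L1_Cf and from 2951 over 8460 to 26430 in L1_Canis1. The 18S and 28S rRNA models, SSU-rRNA_Hsa and LSU-rRNA_Hsa, had 308478 and 265445 reads, and rRNA took 84.4% of the reads in the dog file.

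In horse, whole L1 models of 5921 to 7034 nt led. L1-2_EC had 18538 rebuilt reads (10.6% of element reads), L1-1_EC had 17064 (9.76%), L1-5_EC had 14886 (8.51%) and L1-4B_EC had 12054 (6.89%). L1-2B_EC had 11843 reads and L1-4_EC had 7648. ERE1, a tRNA-derived SINE of horses, had 8502 reads (4.86%). The first LTR element was ERV1-1N-EC_I with 1418 reads (0.811%), and the first DNA transposon Mariner-N1_EC with 484 (0.277%). ERV1 elements together had 7.29% of element reads in horse and 3.51% in dog. The satellite SAT2pl, which is no transposable element, had 9108 reads. The 2 rRNA models had 252141 and 228300 reads, and rRNA took 72.1% of the reads in the horse file.

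In bat the leading models came from several classes. L1-4A_EF had 6558 expected counts (11.7% of element reads), L1-2A_EF had 2083 and L1-1A_EF had 1723. Without L1-4A_EF the LINE share in bat was 14.0%. The Tc/mariner models MLUC.TC2_122_ORF and MLUC.MYOTIS_TC2 had 2375 (4.25%) and 2247 (4.02%). HELITRON-10_EF had 2051 (3.67%), the endogenous retrovirus MLUC.ERV1-9N-I_ML had 2364 (4.23%), and LTR-4_EF-LTR had 1096 (1.961%). PVAM.R368, of unknown class, had 1561, and the first SINE, VES.SUB12, had 724 (1.30%). By the classes in the file, hAT elements took 12.8%, Tc/mariner elements 11.1% and PiggyBac elements 0.399%. MLUC.HAL1-1A_ML, with 2248 expected counts, is filed under hAT, although HAL1 is known as an L1-derived LINE. The 5 HAL1 models filed under hAT held 47.3% of the hAT reads, and counted as LINE they brought LINEs to 30.1% and DNA transposons with Helitrons to 37.7%.

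Families named alike in dog and horse were mostly at a higher TPM in horse. Of 308 elements with reads in either species, 292 were higher in horse and 16 in dog, with a median log2 ratio of 2.60. As shares of element reads, 276 were higher in horse and 32 in dog, with a median of 1.57. Of the 61 with at least 10 reads in both, 58 were higher in horse by TPM and 55 by share. Of the 87 L1 families among the 308 elements, 86 were higher in horse, as were 56 of 58 ERVL families, 28 of 28 MaLR families, 31 of 35 hAT-Charlie families and 21 of 24 Tigger families. MIR, an ancient SINE, had 61.4 reads in horse and 2.05 in dog, a TPM ratio of 33.8 (9.11 to 290). L1MEf_5end had a ratio of 24.4 (9.56 to 95.04). MER44C had 247 reads in horse and none in dog, at least 92.7-fold higher against a floor of 3 reads; MER2 was at least 30.9-fold and MER58B at least 20.49-fold higher. Against element reads in place of TPM these differences were smaller, 17.8 times for MIR, 12.9 times for L1MEf_5end, and at least 48.8, 16.3 and 10.8 times for MER44C, MER2 and MER58B.

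Simple repeats went the other way, with 28 of 39 higher in dog. (GAAA)n was 99.6 times higher in dog (17.5 to 3962), (GGAA)n 40.1 times (13.5 to 198) and (GA)n 15.6 times (8.54 to 34.1). Charlie10 was 4.62 times higher in dog (3.07 to 7.21), and the small nucleolar RNA U3 was 2.45 times higher (1.51 to 4.17). Against element reads these 5 were 189, 76.1, 29.6, 8.78 and 4.65 times higher in dog. The 8 non-coding RNAs with at least 10 reads in both species had horse over dog TPM ratios from 0.408 for U3 to 1.23 for U1 (0.749 to 2.01). Between them lay U2 at 1.22 (0.673 to 2.22), 7SLRNA, which is filed under SINE, at 0.995 (0.791 to 1.25), U6 at 0.809 (0.701 to 0.932), 7SK at 0.718 (0.549 to 0.931), and the 2 rRNA models at 0.969 and 0.921. Of those with fewer reads, 5S rRNA had 11.003 reads in dog and 1.05 in horse, and U4 had 6.002 and none. U17 had none in dog and 3.999 in horse, and U5 had 3.001 and 2.92. U13 and the tRNA models had at most 3.001 reads in either species. Across the 61 elements with at least 10 reads in both species, which are not independent replicates, Spearman's rho of TPM was 0.866 and Pearson's r of log2(TPM + 1) was 0.826.

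**Figure D5:**
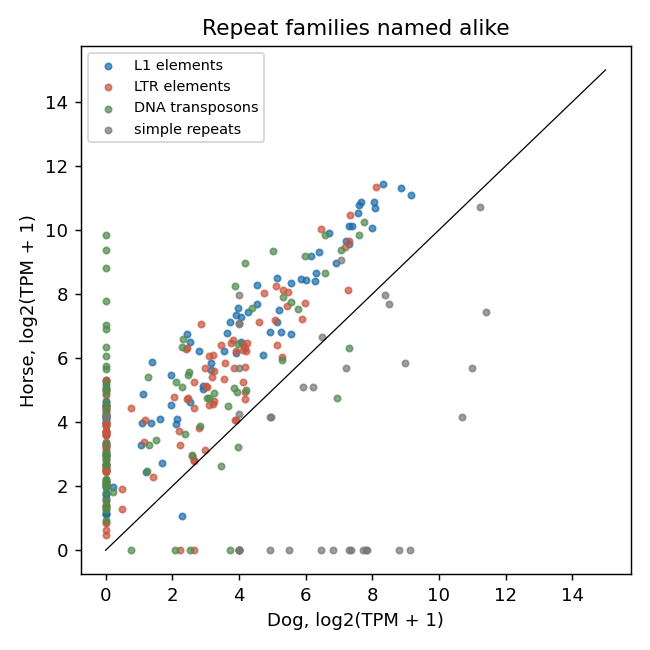
Dog (x axis) and horse (y axis) log2(TPM + 1) of L1, LTR, DNA transposon and simple repeat models named alike, 1 point per model with reads in either library, coloured by group, with the line of equal values. Of the L1 models, which count parts of the same family separately, 86 of 87 lie above the line, and of the simple repeats 28 of 39 lie below it.

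Of the 16 elements named alike in bat and dog, MLT1A0 and MLT1B, both ancient MaLR elements, were 6.41 times (4.02 to 10.5) and 6.14 times (4.35 to 8.87) higher in bat as TPM among elements, and Tigger1 was 1.63 times higher in dog (1.39 to 1.92). Of the 16 named alike in bat and horse, 15 were higher in horse by TPM among elements but 9 by share of element reads, and of the 8 with at least 10 reads in both, 5 were higher in bat by share. MER20 was 9.51 times (3.66 to 37.0), MLT1D 4.59 times (2.77 to 7.65), LTR21B1_EC 3.02 times (2.004 to 4.62) and LTR21B2_EC 2.98 times (1.77 to 5.55) higher in horse, and MIR had 61.4 reads in horse and none in bat. By share of element reads MER20, MLT1D, LTR21B1_EC and LTR21B2_EC were 5.35, 2.57, 1.69 and 1.67 times higher in horse. The related MIRB, chosen after its values were seen, had 24.3 reads in horse and 11.1 expected counts in bat. MIRB was higher in horse by TPM among elements but higher in bat by share of element reads.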

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

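Satellites and simple repeats in the dog and horse mRNA files stand outside the element comparison and had reads above the 3 that a count of 0 allows. Satellites had 10001 rebuilt reads in horse and 257 in dog. Simple repeats had 232 in horse and 871 in dog. With 1 library per group, samples far from their group and differences of effects between groups were not looked for.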

How the results depend on the processing

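Orientation and each measure on oriented sequences, either strand, thinning, 1 sequence per 5-prime end, removal of self-complementary starts, the 95% rule, HAL1 as LINE and shares with at least 10 reads in both were chosen after seeing the data. Of 150 values under alternatives, 29 lay within the error of the main value, 117 are counted as moved and 4 changed direction, in 39 results. The median log2 ratios had no error, so each of their alternatives without a change of sign is counted as moved. The other moved values lay beyond the error. Most intervals cover counting error alone and are narrow. No paired analysis was possible because each group held 1 library. The 24 to 33 nt class was not run, since it takes all reads. Except where fewer sequences or models follow from the setting itself, the cause was not tested. Values are in the order dog, bat, horse. With distinct sequences counted once, 26 to 32 nt sequences were 91.8%, 88.9% and 89.7%, first-base T 43.3%, 42.0% and 43.7%, and A at position 10 30.4%, 27.4% and 29.4%. With at least 2 reads, first-base T was 51.3%, 49.5% and 48.4%, A at position 10 25.2% in bat and 28.5% in horse, the listed overlap ratio 1.21, 1.15 and 1.38, and sharing 0.487% for dog and bat, 0.277% for dog and horse and 0.425% for bat and horse. On either strand, with all sequences, sharing was 0.602%, 0.496% and 0.652% for these pairs. At 28 to 31 nt, first-base T was 53.6%, 50.8% and 49.1% and A at position 10 30.9%, 25.5% and 28.8%. Without known RNAs, first-base T was 53.0%, 52.1% and 48.5% as listed and 69.4%, 79.3% and 78.9% oriented. Orientation gave first-base U of 64.9%, 71.8% and 77.3% and A at position 10 of 34.1%, 23.7% and 32.1%; with 95% of variant reads on one end these were 67.6%, 83.5% and 82.5%, and 30.4%, 23.9% and 30.8%, with overlap ratios of 6.41, 2.09 and 6.47. With each 10-nt start counted once, the overlap ratio fell below 1 as listed (0.946, 0.969 and 0.9504) and was 1.0204, 1.03 and 1.003 oriented. With 1 sequence per 5-prime end it was 1.15, 1.05 and 1.43. Against base composition it was 1.08, 1.06 and 1.20 as listed and 2.37 oriented in dog. With equal numbers of sequences it was 1.13 in dog and 1.28 in horse as listed, and thinned to the bat depth 6.02 in horse oriented. By TPM, LINEs were 20.7%, 2.07% and 15.01%, SINEs 76.6%, 38.7% and 71.6%, LTR elements 2.11%, 9.16% and 10.8%, and DNA transposons with Helitrons 0.598%, 38.2% and 2.60%. Without the leading model, LINEs were 66.8%, 14.0% and 68.1%, SINEs 26.97%, 15.9% and 18.8%, LTR elements 4.58%, 15.2% and 11.4%, and DNA transposons with Helitrons 1.64%, 49.5% and 1.65%. With at least 10 reads per model, LINEs were 71.6% in dog, LTR elements 3.67%, 13.1% and 10.1%, and DNA transposons with Helitrons 1.33% in dog and 1.41% in horse. With HAL1 as LINE, LINEs were 30.1% and DNA transposons with Helitrons 37.7% in bat. The median log2 ratio of elements named alike was, for horse over dog, 3.27 with a pseudocount of 0.1, 1.57 as share of reads and 2.35 with at least 10 reads in both; for bat over dog 0.64, 0.66 and 1.38; and for bat over horse -1.22, -0.32 and -0.67. As share of reads with at least 10 reads in both, it was 1.42 for horse over dog and 1.40 for bat over dog, and it changed sign for bat over horse, to 0.18. Bat had the smallest depth, 5828928 reads and 55904 element counts.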

Other observations

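The tests in this part were chosen after the results were seen, except the listed first-base T share without known RNAs, an alternative fixed before the data were examined. Several abundant piRNA-sized sequences shared between species, outside the fixed list, were fragments of other RNAs. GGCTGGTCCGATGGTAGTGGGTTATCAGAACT, the start of a Y RNA, had 142691 reads in dog and 95866 in horse. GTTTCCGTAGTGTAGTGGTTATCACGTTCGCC, the 5-prime fragment of tRNA-Val, had 125089 reads in dog, 294 in bat and 37581 in horse. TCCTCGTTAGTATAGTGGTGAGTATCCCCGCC, the 5-prime fragment of tRNA-Asp, had 1160, 414 and 3506. The oriented sequence CCAGTGTGAATTCTCTGACGTTGAATGAGC, of no RNA named here, had 73476 reads in dog and 27092 in horse. Of the 1000 most abundant 26 to 32 nt sequences of each library outside the known RNAs, between 1.60% and 3.70% were found in another library on either strand. The 24 nt sequence that led in dog, TGAGAACTGAATTCCATAGGCTGT, holds miR-146b-5p, which was not in the fixed list.

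The bat testis showed a smaller excess of 10-nt overlaps than dog and horse, and with 1 library each, whether the species differ in the ping-pong cycle stays open. Depth alone did not account for it, since dog and horse thinned to the bat depth kept ratios of 3.24 and 6.02. Leaving out known rRNA, tRNA and miRNA fragments gave a bat ratio of 1.27, which leaves these fragments open, since it took out only 296 of 101694 sequences. Whether more orientation errors in bat account for it stays open. Under the stricter rule the bat ratio was 2.09 against 6.41 and 6.47, while its first-base U share, 83.5%, was the highest. That share does not measure orientation errors, since the true share of each species is unknown. In the check on known RNAs most oriented rRNA sequences of bat were wrong, while its tRNA and miRNA sequences were right. Length variants of abundant RNAs may carry much of the difference. With 1 sequence per 5-prime end the ratios were 1.15 in dog (1.13 to 1.17), 1.05 in bat (1.021 to 1.13) and 1.43 in horse (1.36 to 1.50). Horse stayed above both. The dog and bat ranges touch, but they keep self-complementary starts that the ratios leave out. They therefore do not decide whether dog and bat differ under this setting.

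The listed first-base T share near 50% is in line with many sequences being written as the reverse complement of the RNA. Orientation, which looks at no base, raised the U share over the highest of 20 random orientations by at least 14.7 percentage points in the 3 species. Fragments of the RNAs in the fixed list do not account for it, since without them the listed share was at most 53.0%. Fragments of other RNAs, such as those of Y RNA and tRNA-Val named above, were not left out. Sequences on 2 rows began with T and also ended with A more often in dog and horse, in 20.9% against 11.98% of sequences on 1 row with at least 2 reads in dog and 25.3% against 13.6% in horse, while in bat the 16.9% (13.4 to 20.8%) could not be told from 13.8% at this number. No biological explanation was tested.

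Families named alike, in each of the 7 large element classes, were mostly at a higher TPM in horse than in dog. Over all models of a class, the share of element reads was not higher in horse for Tigger (0.902% in dog, 0.877% in horse), hAT-Charlie (0.440% and 0.427%) or L1 (71.34% and 71.27%). It was higher in horse for ERV1, ERVL, MaLR and hAT-Tip100. A scale difference that also covers non-coding RNAs did not account for the higher TPM. The median horse over dog ratio of the 6 non-coding RNAs other than rRNA with at least 10 reads in both was 0.902, and 4 of their intervals lay wholly below 2. These RNAs cannot show a rise of all element reads against them. Elements took 15.3% of all reads in dog and 26.3% in horse, and the median log2 ratio was 2.60 by TPM but 1.57 by share of element reads. A background of reads spread over the genome, such as unspliced RNA or DNA, could raise many families. The medians of the 7 large element classes, from 2.03 to 2.69 on the log2 scale, do not decide it, since the rise depends on the families counted. Among families named alike, reads went from 457 in dog to 747 in horse for hAT-Charlie and from 120.5 to 1028 for Tigger. Over all Tigger models they went from 937 to 1534. Simple repeats were lower in horse, with a median of -3.15 and 28 of 39 lower, while satellites, on models not named alike, had 257 reads in dog and 10001 in horse, and the repeat content of the genomes was not used here. Such a background cannot be told apart from a species difference in element expression, because each species had 1 library and no genic or intergenic counts were used here.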
